A study of Arabidopsis thaliana with 36 samples.

How the data were processed

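Messenger RNA from whole 4-day seedlings of Arabidopsis thaliana was sequenced in 36 libraries, 12 in each of 3 experiments. Per the submitters' processing notes, reads were aligned with TopHat and counted per gene with HTSeq. The tool versions, the genome build, the strand setting and the treatment of reads that match several genes were not given in the sources used here. The deposited table holds gene values in RPM, reads per 1e+06 reads, which the authors computed from those counts, in 1 file with a column for each of the 36 libraries. No coordinates are printed, and gene symbols were taken from a RefSeq annotation table by gene code.

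The values of each library were checked to be whole multiples of 1 step, the value of a single read, with a tolerance of 0.02 reads. All values passed apart from genes that the file lists for gin2 but not for Ler, of which 195 lay on the step of a Ler library and 840 on the library's own step. Those genes were left out. The recovered whole reads were used only for the alternatives that need counts. RPM columns of the ethylene experiment sum to 1e+06 over 33602 genes. The glucose-TOR columns sum to 1e+06 over 19382 listed genes, with genes of low value left blank by the authors. In the glucose-HXK1 experiment 17367 genes are listed for Ler and 18402 for gin2, the columns sum to less than 1e+06, and no chloroplast or mitochondrial genome genes are listed, so part of each denominator lies on genes that the file does not show. A further 17 codes carry a suffix naming the Ler accession and were not used in the tests.

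Reads on listed genes numbered 16.4 to 21.5 M (1e+06) per library in the ethylene experiment, 13.3 to 21.9 M in the glucose-TOR experiment and 5.65 to 13.6 M in the glucose-HXK1 experiment. A floor of 3 reads per library was used where a group was at 0. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

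Genes with at least 1 RPM in at least 3 libraries of an experiment were kept, which left 19442 genes for ethylene, 19336 for glucose-TOR, 17352 for glucose-HXK1 and 17120 for the comparison across the glucose experiments. Values were taken as log2(RPM + 1). Each experiment was fitted across its 12 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend, and each of the 15 comparisons was a contrast of that fit. The comparison of Ler with Col-0 used the 24 libraries of both glucose experiments. A gene was called when its Benjamini-Hochberg adjusted p, two-sided, was below 0.05. Errors of log2 changes are standard errors (SE) from the fit, and errors of RPM are standard deviations (SD) over the 3 libraries of a group.

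Before the data were examined, 24 lists of growth, hormone, sugar, stress and photosynthesis genes were written, along with the comparisons, the tests, the alternatives and the rule for naming genes. Of 422 list entries, 382 matched the annotation by code and symbol, 39 by code alone, and 1 was dropped. Lists with at least 3 tested members were tested with camera from limma, which asks whether a list moved relative to the other genes, with a preset correlation between genes of 0.01. It was run again with an estimated correlation. List p values were adjusted over the lists of a comparison. Overlaps used Fisher's exact test, adjusted over 44 overlaps.

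The named genes follow a rule. For each list called by camera or with at least 3 called members, up to 3 called members with the largest changes were eligible. So were the 5 largest rises and 5 largest falls among called genes with at least 5 RPM in the higher group and no overlap between the libraries of the groups. TOR, HXK1 and, for ethylene, EBF2, ERF1, ETR2 and ERS2 were always eligible, as were the 5 genes with the largest summed changes in each overlap. The text names a selection of the eligible genes.

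Equal replicate numbers were checked for pairing by the correlation of their residuals across genes, where genes are not independent replicates. For mock 4 h against mock 2 h, all 3 pairs had r above 0.1, namely 0.595, 0.411 and 0.382. No other comparison had this in all of its pairs.

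The alternatives were a fit to only the groups compared, median-of-ratios scaling, an added 2-fold minimum, no filter, a pseudocount of 0.25 RPM, a replicate block, edgeR 4.0.16 with TMM, DESeq2 1.42.0, the estimated correlation, other definitions of the gene sets, and leaving out each library in turn. After the data had been seen, 3 more were added. These were RPM recomputed over reads on nuclear genes (nuclear RPM), leaving out 1 tor library with few chloroplast reads, and leaving out both Ler libraries numbered 3. Calling was tested on simulated data with 200 changed genes per comparison. At 2-fold rises 100% of 50 genes were called for ACC at 2 h and glucose in Col-0, and 64% for glucose in Ler. At 1.5-fold these were 100%, 98% and 12%. Unchanged genes were called 12, 16 and 3 times. A wrong split of real Ler libraries called 5198, so these rates may not carry over.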

Results

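Whole seedlings of Arabidopsis thaliana, 4 days old, were profiled by mRNA sequencing in 12 groups of 3 libraries, which the labels call biological replicates. In the ethylene experiment, wild-type Col-0 seedlings grown with glucose received 10 µM ACC, the precursor from which plants make ethylene, or a mock treatment, for 2 h or 4 h. In the glucose-TOR experiment, seedlings grown without glucose in liquid Murashige and Skoog medium were held for 2 h with 15 mM glucose or without it. The genotypes were Col-0 and tor, labelled as an inducible mutant of the growth-promoting kinase TOR. The glucose-HXK1 experiment used the same glucose treatment on the wild type Ler and on gin2, a mutant of HXK1, a hexokinase that also acts as a glucose sensor. Values are group means ± SD in reads per 1e+06 (RPM) over n = 3 libraries, and log2 changes are ± SE. Counts adjusted over the list alone are given where they differ from those over all genes.

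Reads on listed genes numbered 16.4 to 21.5 M (1e+06) per library in the ethylene experiment, 13.3 to 21.9 M in the glucose-TOR experiment and 5.65 to 13.6 M in the glucose-HXK1 experiment. In Ler, a mean of 37.9% ± 14.5 of the RPM total without glucose and 41.3% ± 12.7 with glucose lay on genes not listed. In gin2 the shares were 15.5% ± 2.41 and 16.7% ± 1.41. Reads on chloroplast genome genes made up 0.845% ± 0.422 of RPM in Col-0 without glucose, 0.477% ± 0.195 in Col-0 with glucose, 1.97% ± 0.866 in tor without glucose and 2.43% ± 1.71 in tor with glucose.

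**Figure D1:**
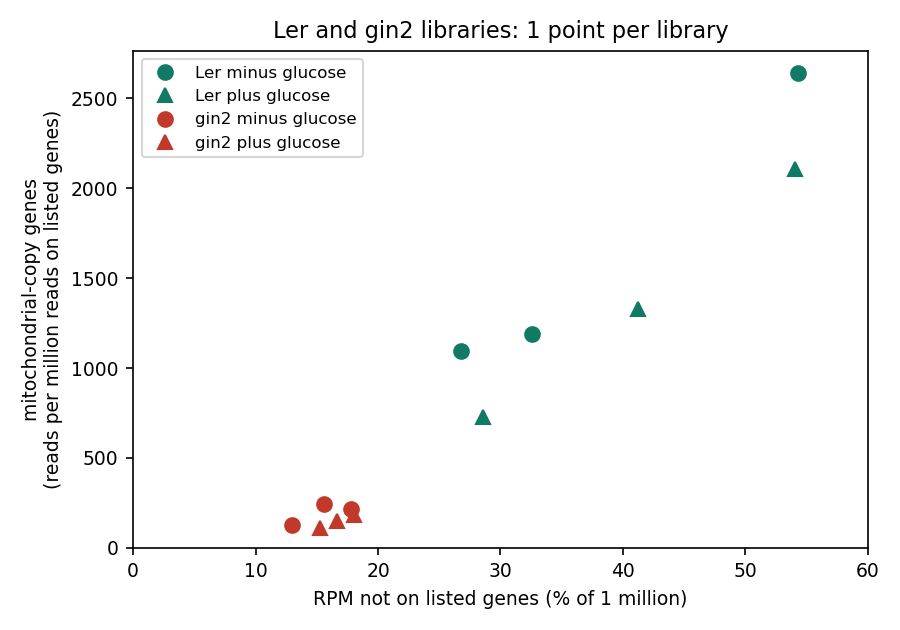
Each point is 1 library of the glucose-HXK1 experiment, with the percentage of RPM on genes not listed on the x axis and the reads on nuclear copies of mitochondrial genes, in RPM of the reads on listed genes, on the y axis, for Ler in green and gin2 in red without glucose (circles) and with glucose (triangles). The share not listed lay between 13.0% and 18.0% in gin2 and between 26.8% and 54.3% in Ler.

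TOR RPM was higher, not lower, in libraries labelled tor, so it does not show a loss of TOR, and tor below means the libraries labelled so. Without glucose, TOR (AT1G50030) stood at 223 ± 0.597 RPM in tor and 115 ± 5.17 RPM in Col-0, a log2 difference of 0.96 ± 0.07 (adjusted p = 3.58e-07). With glucose it stood at 178 ± 8.52 RPM and 96.1 ± 0.811 RPM, a log2 difference of 0.88 ± 0.07 (adjusted p = 4.01e-07). Reads of an RNAi hairpin can count towards TOR, and gin2 can carry a point mutation, so neither level need fall in its mutant. HXK1 (AT4G29130) was at 14.4 ± 0.924 RPM in gin2 and 34.0 ± 10.6 RPM in Ler without glucose, and fell by 1.13 ± 0.25 on the log2 scale (adjusted p = 0.00112, -1.73 with median-of-ratios scaling). With glucose it was at 17.7 ± 0.937 RPM and 50.5 ± 16.3 RPM, and fell by 1.41 ± 0.25 (adjusted p = 0.000107, -2.05 with that scaling). In the ethylene experiment TOR lay between 86.8 and 106.9 RPM and HXK1 between 69.8 and 88.8 RPM.

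**Figure D2:**
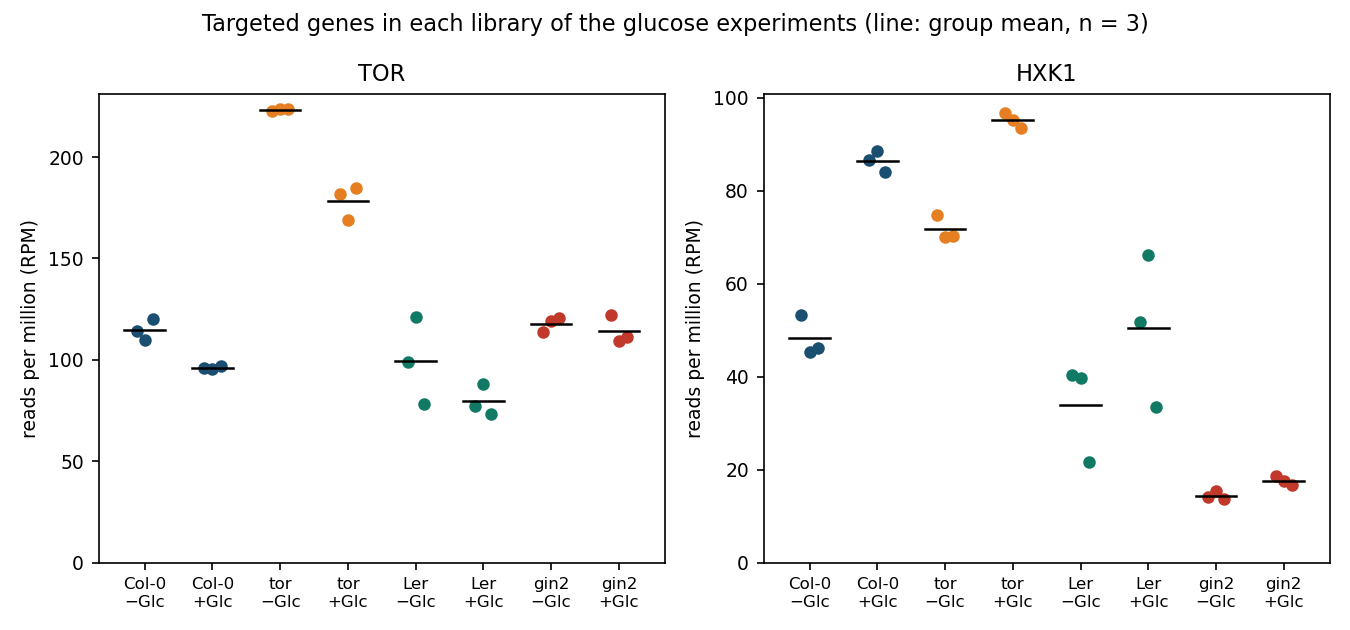
Points are the RPM of TOR and HXK1 in each library of the 8 glucose groups, and black lines are group means. TOR was at 223 RPM in tor and 115 RPM in Col-0 without glucose, and HXK1 was at 17.7 RPM in gin2 and 50.5 RPM in Ler with glucose.

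ACC for 2 h was compared with mock for 2 h to ask which transcripts respond early to the ethylene precursor. The ethylene receptor genes ERS2 (AT1G04310) and ETR2 (AT3G23150) rose by 1.94 ± 0.08 (adjusted p = 3.35e-08, from 11.7 ± 0.625 RPM to 47.4 ± 0.846 RPM) and 1.68 ± 0.09 (adjusted p = 3.62e-07, from 24.3 ± 0.988 RPM to 80.0 ± 3.5 RPM). EBF2 (AT5G25350), whose product removes the transcription factor EIN3, rose by 1.42 ± 0.12 (adjusted p = 6.49e-06), and ERF1 (AT3G23240), a target of EIN3, rose by 1.59 ± 0.15 from a low level (0.134 ± 0.0985 RPM to 2.41 ± 0.246 RPM). ARL (AT2G44080) and ARGOS (AT3G59900), which act on organ size, rose by 2.96 ± 0.11 (from 24.1 ± 3.05 RPM to 195 ± 32.8 RPM) and 2.75 ± 0.12 (adjusted p = 2.9e-08 and 3.88e-08). The expansin gene EXPA5 (AT3G29030), whose product loosens cell walls, fell by 2.38 ± 0.16 (adjusted p = 1.04e-06).

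All 12 genes of ethylene perception and signalling rose (median log2 0.83, camera adjusted p = 2.98e-17, adjusted p = 0.0332 with an estimated correlation). Of 16 ethylene response genes, 12 rose and none fell, including HB52 (AT5G53980) at 2.16 ± 0.15 (median 1.3, camera adjusted p = 2.98e-17, adjusted p = 0.0271 with an estimated correlation). Of 6 ethylene biosynthesis genes 3 rose, led by ACO1 (AT2G19590) at 1.28 ± 0.09 and ACO4 (AT1G05010) at 1.08 ± 0.10, which encode the enzyme of the last step (camera adjusted p = 0.0055, adjusted p = 0.201 with an estimated correlation). Among 15 genes of cell wall loosening and cellulose 4 fell and 1 rose, with EXPB1 (AT2G20750) at -2.19 ± 0.20 and EXPA8 (AT2G40610) at -1.48 ± 0.21 (median -0.11, camera adjusted p = 0.00337, adjusted p = 0.405 with an estimated correlation).

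The next 3 lists were called, but not with an estimated correlation (adjusted p = 0.549 for each). Of 29 sugar starvation genes 8 rose, 9 when adjusted over the list alone, with SEN1 (AT4G35770) at 1.15 ± 0.17 and SEN5 (AT3G15450) at 0.91 ± 0.20 (camera adjusted p = 0.00052). Defence and touch genes rose in 4 of 16 cases, 7 when adjusted over the list alone, among them WRKY40 (AT1G80840) at 1.28 ± 0.17 (camera adjusted p = 0.00666). Root hair genes rose in 3 of 11 cases, 7 when adjusted over the list alone, with EXPA7 (AT1G12560) at 0.74 ± 0.12 (camera adjusted p = 0.00377). The photosynthesis list moved down as a group (median -0.21, camera adjusted p = 5.96e-08, adjusted p = 0.274 with an estimated correlation) although limma called 0 of 34 members. At an unadjusted p below 0.05, 0 of them rose and 11 fell, and edgeR called 1 and DESeq2 3, all downward.

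Outside the called lists, GPT2 (AT1G61800), a plastid sugar phosphate carrier gene, rose by 1.24 ± 0.16. In all, 1799 of 19442 genes were called, 1064 up and 735 down. With median-of-ratios scaling the split was 915 up and 884 down, and 1650 genes were in both. TOR changed by 0.16 ± 0.07 (adjusted p = 0.203) and HXK1 by 0.18 ± 0.06 (adjusted p = 0.111), neither past the threshold.

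**Figure D3:**
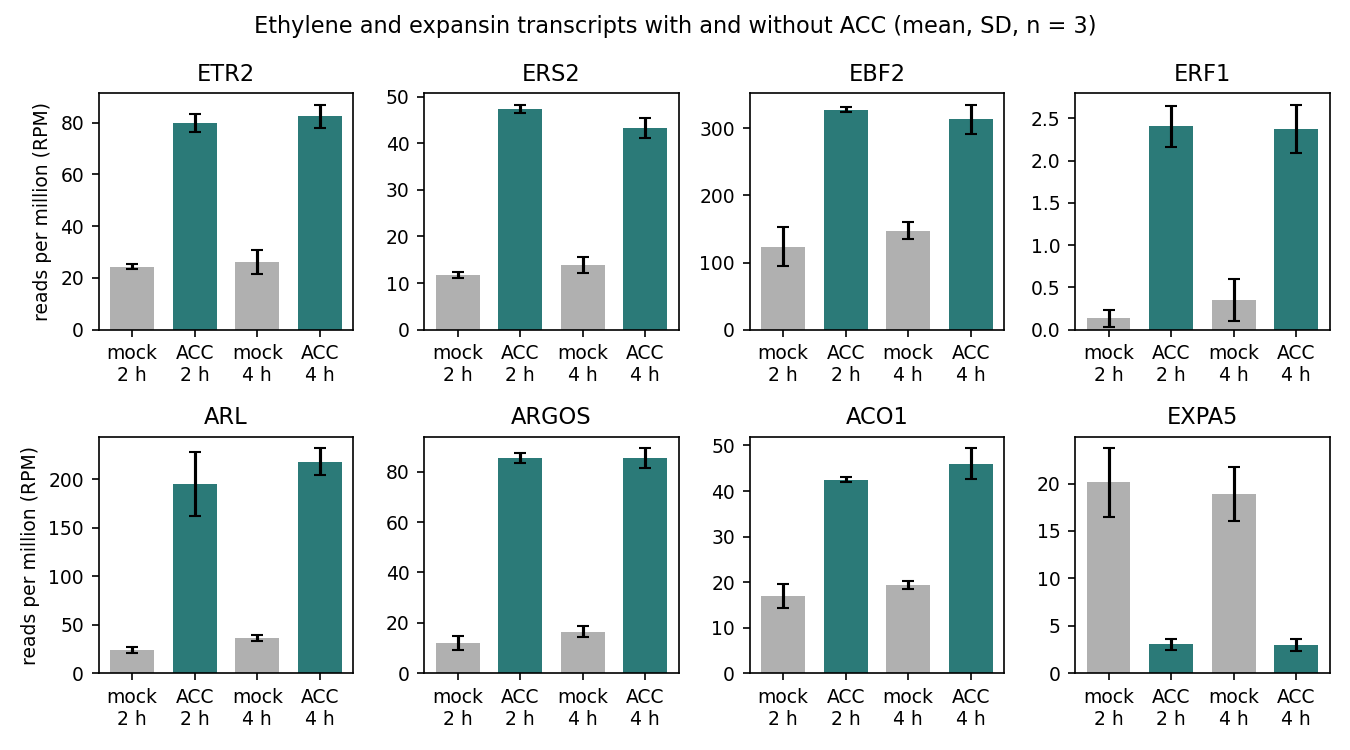
Bars are mean RPM of 8 genes in Col-0 after mock (grey) or ACC (teal) for 2 h and 4 h, with error bars of 1 SD over 3 libraries. ARL stood at 24.1 RPM after mock and 195 RPM after ACC at 2 h, and ERS2 at 11.7 and 47.4 RPM.

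ACC for 4 h was set against mock for 4 h to ask how the response looks later. ARL rose by 2.56 ± 0.11 (adjusted p = 1.2e-07, from 36.2 ± 3.06 RPM to 218 ± 13.9 RPM), HB52 by 2.40 ± 0.15, ETR2 by 1.64 ± 0.09, ERS2 by 1.58 ± 0.08, EBF2 by 1.08 ± 0.12 and ERF1 by 1.34 ± 0.15. The peroxidase gene AT5G19890 rose by 3.80 ± 0.44 (adjusted p = 6.48e-05, from 10.4 ± 8.84 RPM to 133 ± 36.5 RPM). EXPA5 fell by 2.32 ± 0.16 and EXPA1 (AT1G69530) fell by 1.2 ± 0.14 (from 200.4 ± 6.99 RPM to 87.2 ± 14.1 RPM). LHCB6 (AT1G15820), a gene of the light-harvesting antenna, fell by 1.21 ± 0.23 (adjusted p = 0.00302, from 834 ± 36.2 RPM to 366 ± 74.1 RPM). The neighbouring similar genes AT5G46900 and AT5G46890 fell by 3.81 ± 0.18 and 3.57 ± 0.22, values that are uncertain because how shared reads were counted is not known.

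Of 12 ethylene perception and signalling genes 11 rose, and 12 when adjusted over the list alone (median log2 0.66, camera adjusted p = 9.97e-11, adjusted p = 0.104 with an estimated correlation). Ethylene response genes rose in 11 of 16 cases (median 1.15, camera adjusted p = 6.65e-08, adjusted p = 0.104 with an estimated correlation), and over the list alone 11 rose and 1 fell. Cell wall genes fell in 8 of 15 cases, 11 when adjusted over the list alone (median -0.38, camera adjusted p = 2.15e-07, adjusted p = 0.104 with an estimated correlation). Photosynthesis genes fell in 18 of 34 cases and in 21 when adjusted over the list alone (median -0.31, camera adjusted p = 9.97e-11, adjusted p = 0.134 with an estimated correlation).

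Of 29 sugar starvation genes 12 rose and 2 fell, with SEN1 at 1.62 ± 0.17 and BCAT2 (AT1G10070) at 0.93 ± 0.14 (camera adjusted p = 0.0317, adjusted p = 0.676 with an estimated correlation). The mitosis list moved down as a group with 2 of 28 genes down and 1 up, 1 and 0 over the list alone, led by CYCD3;1 (AT4G34160) at -0.42 ± 0.08 (median -0.12, camera adjusted p = 0.0105, adjusted p = 0.676 with an estimated correlation). Biosynthesis genes were not called as a list (camera adjusted p = 0.114), with 3 of 6 up, among them ACO1 at 1.21 ± 0.09. In all, 3773 genes were called, 2047 up and 1726 down. With median-of-ratios scaling 3448 were called, and the share that rose went from 54.2% to 42.4%, at 1462 up and 1986 down. Without mock 4 h replicate 2, mock 4 h replicate 3 or ACC 4 h replicate 1 the count was 2462, 2428 or 2477. TOR was at -0.02 ± 0.07 (adjusted p = 0.845) and HXK1 at 0.13 ± 0.06 (adjusted p = 0.163).

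The change of the ACC effect from 2 h to 4 h was tested as an interaction. AT5G46900 was at 25.1 ± 6.94 RPM in mock and 8.53 ± 0.724 RPM in ACC at 2 h, and at 28.3 ± 2.86 RPM and 1.1 ± 0.349 RPM at 4 h, so that its effect fell by 2.39 ± 0.25 (adjusted p = 0.0055). The effect on SIAR1 (AT1G44800), an amino acid transporter gene, fell by 1.01 ± 0.12 (adjusted p = 0.0177), that on ATCSLB05 (AT4G15290), a cellulose synthase-like gene, fell by 1.55 ± 0.23 (adjusted p = 0.0448), and that on AT2G22122 rose by 0.84 ± 0.11 (adjusted p = 0.0287). The ethylene genes EBF2, ERF1, ETR2 and ERS2 changed by -0.34 ± 0.17, -0.25 ± 0.21, -0.04 ± 0.13 and -0.36 ± 0.11, none past the threshold (adjusted p = 0.641, 0.769, 0.946 and 0.513). Of the called genes named here, AT5G46900 alone stayed called under each alternative and without each library. TOR was at -0.18 ± 0.10 (adjusted p = 0.655) and HXK1 at -0.05 ± 0.09 (adjusted p = 0.905).

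In all, 7 genes were called, 1 up and 6 down, with 1555 at an unadjusted p below 0.05, and edgeR called 8 and DESeq2 55. No member of any list was called by limma, edgeR or DESeq2. Camera still placed 10 lists apart from the other genes. The ethylene response list lay lower (median -0.31, camera adjusted p = 0.00069, 7 of its genes down at an unadjusted p below 0.05), as did mitosis (median -0.19, camera adjusted p = 0.00069, 5 down), cell wall (median -0.22, camera adjusted p = 0.0012, 2 down adjusted over the list alone) and photosynthesis (median -0.15, camera adjusted p = 0.000949, 5 down). Ribosomal protein genes lay higher (median 0.12, camera adjusted p = 0.00069, 3 up and 1 down). None of the 10 was called with an estimated correlation (adjusted p = 0.469 to 0.499). The count moved with single libraries. It was 1 without mock 2 h replicate 3, any mock 4 h replicates, ACC 2 h replicate 1, ACC 2 h replicate 2 or ACC 4 h replicate 3. Without ACC 4 h replicate 1 it was 2, without ACC 4 h replicate 2 it was 3, and without ACC 2 h replicate 3 it was 288.

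Mock at 4 h was compared with mock at 2 h to measure what time alone changed. FER1 (AT5G01600), which encodes the iron store ferritin, rose by 1.25 ± 0.15 (adjusted p = 0.0099, from 42.8 ± 6.72 RPM to 102 ± 7.1 RPM), while ZIF1 (AT5G13740) and IRT2 (AT4G19680), induced under iron shortage, fell by 1.61 ± 0.18 (adjusted p = 0.00806) and 0.92 ± 0.11 (adjusted p = 0.00806). BTS (AT3G18290), which encodes a ligase of the iron deficiency response, fell by 1.27 ± 0.17 (adjusted p = 0.0212). Under alternatives or without 1 library, the calls of BTS, FER1, ZIF1 and IRT2 ended in 5, 3, 1 and 1 settings. Camera called 4 lists. Ribosome biogenesis lay higher (median 0.14, camera adjusted p = 3.84e-08), as did mitosis (median 0.17, camera adjusted p = 3.2e-05), and heat shock lay lower (median -0.40, camera adjusted p = 0.000666, 2 down adjusted over the list alone), as did photosynthesis (median -0.07, camera adjusted p = 0.0191, with 1 up over the list alone). None of the 4 was called with an estimated correlation (adjusted p = 0.695). Limma called 0 of the 30 ribosome biogenesis genes, with 11 up at an unadjusted p below 0.05 and 0 by edgeR and DESeq2. TOR was at 0.09 ± 0.07 (adjusted p = 0.772) and HXK1 at 0.02 ± 0.06 (adjusted p = 0.956).

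In all, 11 genes were called between the mock groups, 3 up and 8 down, with 1533 at an unadjusted p below 0.05, and edgeR called 8 and DESeq2 63. Because replicate numbers paired these groups, a fit with a replicate block is given beside it. It called 21 genes, 5 up and 16 down, and held 10 of the 11. Leaving out mock 2 h replicate 1, mock 2 h replicate 3 or mock 4 h replicate 2 gave 2, 5 or 3 genes. Leaving out mock 4 h replicate 3 gave 0 by limma, with 1096 at an unadjusted p below 0.05.

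Glucose in Col-0 was compared with no glucose to ask which transcripts respond to sugar in the wild type. Genes known as dark- and starvation-induced fell, with SEN5 down from 1102 ± 275 RPM to 2.18 ± 0.527 RPM (log2 -8.42 ± 0.18, adjusted p = 1.03e-11) and the asparagine synthetase gene DIN6 (AT3G47340) at -7.25 ± 0.30 (adjusted p = 1.61e-09). GBSS1 (AT1G32900), of starch synthesis, rose by 5.43 ± 0.28 (adjusted p = 7.79e-09, from 1.06 ± 0.711 RPM to 85.4 ± 12.2 RPM) and GPT2 by 5.31 ± 0.41 (from 1.93 ± 1.74 RPM to 106 ± 27.0 RPM). PAP1 (AT1G56650), a regulator of anthocyanin, rose by 4.61 ± 0.21, and FIB2 (AT4G25630), whose fibrillarin product acts in ribosomal RNA processing, rose by 3.26 ± 0.14 (adjusted p = 2.23e-09, from 26.3 ± 3.47 RPM to 259.6 ± 15.0 RPM). The nitrate reductase genes NIA1 (AT1G77760) and NIA2 (AT1G37130) fell by 4.85 ± 0.19 and 3.97 ± 0.17, and the replication clamp gene PCNA1 (AT1G07370) rose by 2.27 ± 0.24.

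All 30 sugar starvation genes fell (median log2 -3.92, camera adjusted p = 6.96e-29, adjusted p = 0.0539 with an estimated correlation). All 30 ribosome biogenesis genes rose (median 1.82, camera adjusted p = 1.19e-10, adjusted p = 0.49 with an estimated correlation), as did 35 of 37 ribosomal protein genes (median 0.95, camera adjusted p = 1.84e-10, adjusted p = 0.457 with an estimated correlation). DNA replication genes rose in 25 of 27 cases (median 1.48, camera adjusted p = 2.02e-06, adjusted p = 0.567 with an estimated correlation). Mitosis genes rose in 13 of 27 cases, 12 when adjusted over the list alone (median 0.50, camera adjusted p = 0.0186, adjusted p = 0.654 with an estimated correlation). All 5 heat shock genes rose, with HSP70 (AT3G12580) at 4.11 ± 0.18 (median 2.05, camera adjusted p = 0.00897, adjusted p = 0.457 with an estimated correlation).

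Ethylene perception and signalling genes fell in 10 of 12 cases, with EBF2 at -1.23 ± 0.13 (median -0.66, camera adjusted p = 0.000114, adjusted p = 0.457 with an estimated correlation), and ethylene response genes fell in 7 and rose in 2 of 15 (median -0.49, camera adjusted p = 0.00933, adjusted p = 0.49 with an estimated correlation). Photosynthesis genes fell in 11 and rose in 4 of 34 cases, with CP12-2 (AT3G62410) at -1.44 ± 0.26 (median -0.24, camera adjusted p = 0.00933, adjusted p = 0.654 with an estimated correlation). Flavonoid genes rose in 10 and fell in 2 of 13 (median 1.49, camera adjusted p = 0.0126, adjusted p = 0.567 with an estimated correlation). Root hair genes rose in 8 of 10, 9 when adjusted over the list alone, with LRX2 (AT1G62440) at 2.26 ± 0.16 (median 1.48, camera adjusted p = 0.0151, adjusted p = 0.577 with an estimated correlation).

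In all, 10883 of 19336 genes were called, 6909 up and 3974 down. The median of all genes was 0.14 in RPM, and changes relative to it are lower by that amount. With median-of-ratios scaling 5588 rose and 5876 fell. TOR fell by 0.25 ± 0.07 (adjusted p = 0.00753) and HXK1 rose by 0.83 ± 0.08 (adjusted p = 1.67e-06).

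The glucose comparison in libraries labelled tor asked which transcripts responded there. GPT2 rose by 6.65 ± 0.41 (adjusted p = 2.23e-07, from 2.63 ± 2.18 RPM to 329 ± 78.4 RPM) and GBSS1 by 5.13 ± 0.28. SEN5 fell by 5.50 ± 0.18 (adjusted p = 2.4e-09, from 1533 ± 103 RPM to 33.2 ± 5.33 RPM) and DIN6 fell by 4.52 ± 0.30. FIB2 rose by 1.43 ± 0.14 (adjusted p = 1.05e-05, from 40.1 ± 8.52 RPM to 109 ± 12.4 RPM) and PAP1 by 2.16 ± 0.21.

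All 30 sugar starvation genes fell (median log2 -2.52, camera adjusted p = 4.54e-32, adjusted p = 0.0393 with an estimated correlation). A further 6 lists were called, but not with an estimated correlation (adjusted p = 0.894 for each). Ribosomal protein genes rose in 34 of 37 cases, 35 over the list alone (median 0.47, camera adjusted p = 2.42e-09) and ribosome biogenesis genes in 23 of 30 (median 0.69, camera adjusted p = 2.8e-07). Photosynthesis genes fell in 14 of 34, 17 when adjusted over the list alone (9 by edgeR and 11 by DESeq2, median -0.50, camera adjusted p = 5.06e-06), and DNA replication genes rose in 8 of 27, 7 over the list alone (median 0.41, camera adjusted p = 0.0152). Clock genes fell in 5 of 9, with PRR7 (AT5G02810) at -1.36 ± 0.21 (camera adjusted p = 0.0303), and flavonoid genes rose in 7 and fell in 2 of 13 (camera adjusted p = 0.0395).

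Limma called 0 of 10 root hair genes in tor, with 0 at an unadjusted p below 0.05 and 0 by edgeR and DESeq2. In all, 6710 genes were called, 3840 up and 2870 down (median of all genes 0.05), and 3425 up and 3716 down with median-of-ratios scaling. Without tor plus glucose replicate 1, which had the fewest chloroplast reads of its group (0.49% of RPM), 3286 rose and 3631 fell (median of all genes -0.02). TOR fell by 0.32 ± 0.07 (adjusted p = 0.00313) and HXK1 rose by 0.40 ± 0.08 (adjusted p = 0.0017).

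**Figure D4:**
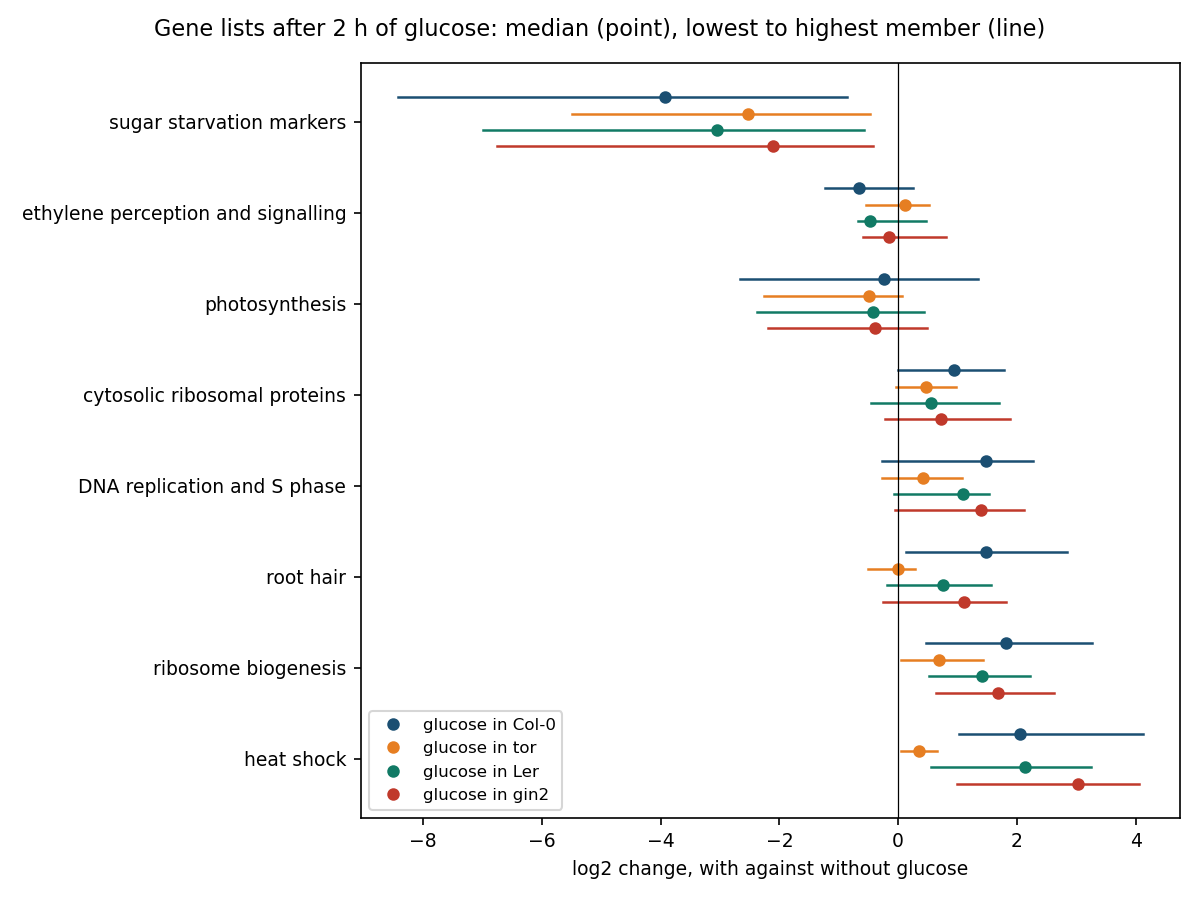
Points are the median log2 change with against without glucose (x axis) of 8 gene lists in Col-0, tor, Ler and gin2, and lines run from the lowest to the highest member. The sugar starvation list had medians of -3.92 in Col-0, -2.52 in tor, -3.04 in Ler and -2.11 in gin2.

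The interaction asked which glucose effects differed between tor and Col-0, where a positive value means a higher effect in tor. The effect on SEN1 was 4.15 ± 0.42 higher (adjusted p = 0.000126), that on NIA1 3.17 ± 0.26 (adjusted p = 2.92e-05) and that on SEN5 2.92 ± 0.26 (adjusted p = 3.5e-05). The effect on HSP70 fell by 3.46 ± 0.25 (adjusted p = 1.72e-05), on FIB2 it fell by 1.83 ± 0.20 (adjusted p = 0.00018) and on PAP1 it fell by 2.45 ± 0.30 (adjusted p = 0.000361). On EBF2 it was 1.43 ± 0.18 higher (adjusted p = 0.000441).

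Sugar starvation genes had higher effects in 24 of 30 cases, 27 when adjusted over the list alone, that is, smaller falls (median log2 1.37, camera adjusted p = 3.99e-26, adjusted p = 0.0724 with an estimated correlation). Effects were lower in 25 of 30 ribosome biogenesis genes, 27 over the list alone (mean -1.08, camera adjusted p = 3.86e-12, adjusted p = 0.329 with an estimated correlation). They were lower in 21 of 37 ribosomal protein genes, 28 over the list alone (11 by edgeR and 16 by DESeq2, median -0.52, camera adjusted p = 1.16e-07, adjusted p = 0.347 with an estimated correlation), and in 17 of 27 DNA replication genes, 21 over the list alone (9 by edgeR and 15 by DESeq2, median -1.05, camera adjusted p = 2.14e-07, adjusted p = 0.405 with an estimated correlation). Root hair genes had lower effects in 6 of 10, 7 over the list alone (median -1.48, camera adjusted p = 0.000275, adjusted p = 0.347 with an estimated correlation).

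Ethylene perception and signalling genes had higher effects in 8 of 12 cases (median 0.76, camera adjusted p = 2.14e-07) and ethylene response genes in 6 of 15, with 8 higher and 1 lower over the list alone (median 0.62, camera adjusted p = 0.000224). Heat shock genes had lower effects in 4 of 5 (median -1.70, camera adjusted p = 0.000466), nitrate genes higher in 6 and lower in 2 of 13 (median 0.35, camera adjusted p = 0.00673) and root meristem genes lower in 2 of 5, 4 over the list alone (median -0.64, camera adjusted p = 0.0212). None of these 5 was called with an estimated correlation (adjusted p = 0.242). Flavonoid genes had lower effects in 6 and higher in 1 of 13, 7 and 1 over the list alone (3 and 1 by edgeR and DESeq2, camera adjusted p = 0.0213, adjusted p = 0.549 with an estimated correlation), and mitosis genes in 1 of 27 (median -0.34, camera adjusted p = 0.0227, adjusted p = 0.838 with an estimated correlation).

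In all, 3361 genes differed, 1200 with a higher and 2161 with a lower effect in tor, against a median of all genes of -0.10 (-0.18 without tor plus glucose replicate 1). With median-of-ratios scaling 2042 were higher and 1966 lower. Without Col-0 plus glucose replicate 2 the count was 2156, and without tor plus glucose replicate 1 it was 5009. Medians of genes chosen by a 2-fold effect in Col-0 can be too large there. They were 1.34 in Col-0 and 0.62 in tor (2151 rose) and -1.46 and -0.88 (1126 fell). TOR was at -0.07 ± 0.10 (adjusted p = 0.673) and HXK1 fell by 0.43 ± 0.11 (adjusted p = 0.0209), a call that ended with median-of-ratios scaling (-0.31), and without Col-0 minus glucose replicate 3 (-0.40), Col-0 plus glucose replicate 1 (-0.42) or 2 (-0.41), or tor minus glucose replicate 1 (-0.40).

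Libraries labelled tor were compared with Col-0 within each glucose state, to ask how they differed in each. Without glucose, AT1G33320 was at 129.8 ± 24.8 RPM in tor and 0.253 ± 0.105 RPM in Col-0 (log2 6.69 ± 0.15, adjusted p = 1.72e-11). The carbonic anhydrase gene CA1 (AT3G01500) fell by 2.31 ± 0.25 (from 4678 ± 368 RPM to 949.5 ± 132 RPM). HSP70 was 3.05 ± 0.18 higher, ETR2 1.39 ± 0.14 and ACO4 1.54 ± 0.18, and DIN6 fell by 1.64 ± 0.30.

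Of 37 ribosomal protein genes 20 were lower and 1 higher without glucose (median log2 -0.30, camera adjusted p = 1.66e-07), and of 34 photosynthesis genes 20 were lower and 8 higher, 21 and 8 over the list alone (median -0.87, camera adjusted p = 6.07e-06). Of 30 sugar starvation genes 10 were lower and 6 higher (median -0.23, camera adjusted p = 0.00865), of 5 heat shock genes 4 were higher (median 1.83, camera adjusted p = 0.027), and of 27 DNA replication genes 4 were lower and 1 higher, 0 and 1 over the list alone (median -0.12, camera adjusted p = 0.027). Scaled by median of ratios, 33, 21, 18 and 11 ribosomal protein, photosynthesis, starvation and replication genes were lower and 0, 2, 4 and 0 higher (33, 21, 18 and 12 lower by DESeq2). None of these 5 lists was called with an estimated correlation (adjusted p = 0.812). In all, 10704 genes differed, 7802 higher and 2902 lower, around a median of all genes of 0.24. With median-of-ratios scaling 4819 were higher and 5269 lower. HXK1 was 0.56 ± 0.08 higher (adjusted p = 6.33e-05).

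With glucose, SEN1 was at 310.3 ± 154 RPM in tor and 24.9 ± 4.87 RPM in Col-0 (log2 3.47 ± 0.30, adjusted p = 8.1e-07) and SEN5 at 33.2 ± 5.33 RPM and 2.18 ± 0.527 RPM. ERS2 was 2.54 ± 0.15 higher (adjusted p = 6.3e-08, 89.5 ± 17.1 RPM against 14.4 ± 0.876 RPM) and ETR2 2.18 ± 0.14. MCM3 (AT5G46280), of the replication helicase, fell by 1.87 ± 0.23 (from 39.7 ± 2.81 RPM to 10.3 ± 2.53 RPM), the D-type cyclin gene CYCD3;1 fell by 1.17 ± 0.12 (adjusted p = 4.09e-06) and NOP5-1 (AT5G27120) fell by 2.03 ± 0.28.

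Ribosomal protein genes were lower in 34 of 37 cases with glucose (median log2 -0.75, camera adjusted p = 7.02e-13), ribosome biogenesis genes in all 30 (median -1.14, camera adjusted p = 5.47e-11) and DNA replication genes in 24 of 27 (median -1.15, camera adjusted p = 3.35e-08). Sugar starvation genes were higher in 23 and lower in 1 of 30, 24 and 1 over the list alone (median 1.13, camera adjusted p = 1.47e-05). Ethylene perception and signalling genes were higher in 11 of 12 (median 0.96, camera adjusted p = 4.52e-05), and ethylene response genes in 13 of 15 (median 0.93, camera adjusted p = 0.000308). Root hair genes were lower in 8 of 10 (camera adjusted p = 0.000524). These 7 calls were lost with an estimated correlation (adjusted p = 0.556). Photosynthesis genes were lower in 22 and higher in 4 of 34, 23 and 4 over the list alone (median -1.07, camera adjusted p = 1.45e-05, adjusted p = 0.616 with an estimated correlation), mitosis genes lower in 8 of 27 (13 by edgeR and DESeq2, median -0.32, camera adjusted p = 0.00348, adjusted p = 0.616 with an estimated correlation), and flavonoid genes lower in 8 and higher in 1 of 13 (median -0.83, camera adjusted p = 0.00359, adjusted p = 0.567 with an estimated correlation). In all, 11881 genes differed, 7214 higher and 4667 lower (median of all genes 0.14, or 0.06 without tor plus glucose replicate 1), and 6008 and 6256 with median-of-ratios scaling. HXK1 was at 0.14 ± 0.08 (adjusted p = 0.146).

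Glucose in Ler was compared with no glucose as the wild-type response beside gin2. DIN6 fell by 6.98 ± 0.24 (adjusted p = 4.54e-18, from 896 ± 329 RPM to 5.74 ± 0.686 RPM) and SEN5 fell by 6.38 ± 0.27 (adjusted p = 2.92e-16, from 1885 ± 648 RPM to 21.5 ± 7.55 RPM). GPT2 rose by 4.44 ± 0.24 (adjusted p = 3.48e-14, from 1.81 ± 0.28 RPM to 60.4 ± 11.1 RPM) and HSFA2 (AT2G26150), a heat shock regulator gene, by 3.24 ± 0.22 (adjusted p = 5.32e-12). FIB2 rose by 2.05 ± 0.22 (from 30.7 ± 5.27 RPM to 131 ± 27.5 RPM) and NIA1 fell by 3.90 ± 0.24.

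Sugar starvation genes fell in 29 of 30 cases, all 30 when adjusted over the list alone (median log2 -3.04, camera adjusted p = 9.03e-52, adjusted p = 0.103 with an estimated correlation). Ribosome biogenesis genes rose in 27 of 29, all 29 over the list alone (median 1.42, camera adjusted p = 1.06e-17, adjusted p = 0.255 with an estimated correlation), and DNA replication genes in 24 of 27, 25 over the list alone (median 1.1, camera adjusted p = 3.08e-10, adjusted p = 0.656 with an estimated correlation). Heat shock genes rose in 4 of 5 (median 2.14, camera adjusted p = 0.000195, adjusted p = 0.255 with an estimated correlation). Photosynthesis genes fell in 11 of 34 (median -0.42, camera adjusted p = 1.5e-05), ribosomal protein genes rose in 13 of 37, 18 over the list alone (median 0.54, camera adjusted p = 0.000195), flavonoid genes rose in 7 and fell in 1 of 11 (median 1.31, camera adjusted p = 0.0164), and root hair genes rose in 5 of 9 (median 0.75, camera adjusted p = 0.0456). Those 4 calls were lost with an estimated correlation (adjusted p = 0.695). Scaled by median of ratios, 20 photosynthesis genes fell, and 27 ribosomal protein genes rose and 2 fell (DESeq2 21, 28 and 2), and the flavonoid and root hair calls ended (adjusted p = 0.0561 and 0.138).

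Ethylene perception and signalling genes were not called as a list in Ler (median -0.47, camera adjusted p = 0.0659), with 2 of 12 down. With median-of-ratios scaling 10 fell and 1 rose, and the list was called (camera adjusted p = 0.0156). In all, 4986 of 17352 genes were called, 3019 up and 1967 down (median of all genes 0.10). Scaling by median of ratios gave 4389 up and 4415 down. TOR was at -0.30 ± 0.22 (adjusted p = 0.326) and HXK1 at 0.56 ± 0.25 (adjusted p = 0.0956). Seed storage transcripts took 0.046% ± 0.052 of the reads on listed genes without glucose and 0.0839% ± 0.0483 with glucose.

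The same comparison in gin2 asked what glucose did in the HXK1 mutant. DIN6 fell by 6.76 ± 0.24 (adjusted p = 1.1e-17, from 865 ± 52.2 RPM to 6.99 ± 0.191 RPM) and NIA1 fell by 4.53 ± 0.24. HSFA2 rose by 4.05 ± 0.22 (adjusted p = 1.07e-13, from 2.37 ± 0.494 RPM to 54.6 ± 4.35 RPM), HSP70 by 3.31 ± 0.28, FIB2 by 2.35 ± 0.22 (adjusted p = 3.24e-09, from 27.0 ± 1.12 RPM to 142 ± 3.79 RPM) and PCNA1 by 2.12 ± 0.23.

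Sugar starvation genes fell in 28 of 30 cases (median log2 -2.11, camera adjusted p = 1.41e-42), ribosome biogenesis genes rose in all 29 (median 1.69, camera adjusted p = 9.49e-23), and heat shock genes rose in 4 of 5 (median 3.03, camera adjusted p = 6.97e-07). Each of these 3 calls was lost with an estimated correlation (adjusted p = 0.0957). DNA replication genes rose in 25 of 27 (median 1.4, camera adjusted p = 6.81e-14, adjusted p = 0.407 with an estimated correlation). Ribosomal protein genes rose in 22 of 37, 26 over the list alone (median 0.71, camera adjusted p = 1.93e-06), photosynthesis genes fell in 7 of 34 (median -0.40, camera adjusted p = 1.03e-05), flavonoid genes rose in 9 and fell in 1 of 11, 9 and 2 over the list alone (camera adjusted p = 0.00264), root hair genes rose in 6 of 9 (median 1.11, camera adjusted p = 0.00455) and defence and touch genes fell in 5 of 12 (median -0.32, camera adjusted p = 0.00693). Those 5 calls were lost with an estimated correlation (adjusted p = 0.709), and that of defence also with median-of-ratios scaling (adjusted p = 0.0563). Of photosynthesis genes edgeR called 21 down and DESeq2 22, and each called 7 ethylene perception and 6 mitosis genes down, where limma called 0. The ethylene response list, not called (camera adjusted p = 0.468), had a median of 0.13, a mean of -0.04 and a test direction of down. In all, 4766 genes were called, 3252 up and 1514 down (median of all genes 0.13), and with median-of-ratios scaling 3946 up and 4114 down. TOR was at -0.05 ± 0.22 (adjusted p = 0.906) and HXK1 at 0.28 ± 0.25 (adjusted p = 0.45).

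The gin2 interaction asked which glucose effects depend on HXK1. The effect on GPT2 fell by 3.38 ± 0.34 (adjusted p = 1.44e-06), with gin2 at 1.91 ± 0.831 RPM without glucose and 5.0 ± 1.41 RPM with it. The effect on SEN5 was 2.82 ± 0.38 higher (adjusted p = 0.000304), with gin2 at 2066 ± 166 RPM and 175 ± 20.5 RPM. It was 2.53 ± 0.35 higher on FBA5 (AT4G26530), an aldolase gene (adjusted p = 0.000304), and 2.19 ± 0.36 higher on TPS8 (AT1G70290), of the trehalose phosphate synthase family (adjusted p = 0.00251). Sugar starvation genes had higher effects in 8 of 30 cases, 15 when adjusted over the list alone, 17 by edgeR and 18 by DESeq2 (median log2 0.78, camera adjusted p = 4.54e-32), and heat shock lay higher as a list (median 0.89, camera adjusted p = 4.03e-06), neither called with an estimated correlation (adjusted p = 0.177). Limma called 0 of the 5 heat shock genes, with 4 up at an unadjusted p below 0.05, 4 when adjusted over the list alone, and 0 by edgeR and DESeq2.

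Ribosome biogenesis lay higher (median 0.26, camera adjusted p = 0.00101), DNA replication higher (median 0.27, camera adjusted p = 0.0103) and nitrate lower (median -0.33, camera adjusted p = 0.006) in this interaction, none called with an estimated correlation (adjusted p = 0.938). In all, 51 genes were called, 41 with a higher and 10 with a lower effect in gin2, with 587 at an unadjusted p below 0.05. The count was 336 with median-of-ratios scaling, 256 higher and 80 lower. Without Ler minus glucose replicate 2 or Ler plus glucose replicate 1 the count was 20. Without gin2 minus glucose replicates 1, 2 or 3 it was 31, 23 or 27. Without gin2 plus glucose replicates 2 or 3 it was 29 or 21. Without Ler plus glucose replicate 2 or Ler minus glucose replicate 3 it was 94 or 212. Medians of genes chosen by a 2-fold effect in Ler can be too large there. They were 1.27 in Ler and 1.31 in gin2 (1102 rose) and -1.46 and -1.11 (995 fell). TOR was at 0.25 ± 0.30 and HXK1 at -0.28 ± 0.35 (adjusted p = 1 for each).

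gin2 was compared with Ler within each glucose state. In RPM the median of all genes lay above 0, at 0.55 without glucose and 0.62 with glucose, so values with median-of-ratios scaling stand beside those in RPM. Without glucose the seed storage gene SESA3 (AT4G27160) fell by 3.81 ± 0.55 (adjusted p = 2.68e-05, -4.31 scaled, from 60.6 ± 55.2 RPM to 2.34 ± 2.18 RPM). The glucosidase gene DIN2 (AT3G60140) was 2.19 ± 0.26 higher (adjusted p = 1.75e-06, 1.59 scaled) and NIA1 1.5 ± 0.24 (0.87 scaled). TOR was at 0.26 (adjusted p = 0.298) in RPM and -0.36 scaled.

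Seed storage genes were lower in 6 of 8 cases without glucose, all 8 when adjusted over the list alone (median log2 -2.46, camera adjusted p = 7.04e-22, adjusted p = 0.115 with an estimated correlation). Root hair genes were lower in 5 and higher in 1 of 9 (median -0.83, camera adjusted p = 5.89e-12, adjusted p = 0.14 with an estimated correlation). Because camera compares a list with the other genes, lists with medians above 0 but below the other genes tested as down, and the calls of their members changed with the scaling. Photosynthesis genes were higher in 8 and lower in 4 of 34, 5 and 4 over the list alone (2 and 17 scaled, camera adjusted p = 5.37e-07, adjusted p = 0.711 with an estimated correlation). Ribosomal protein genes were higher in 6 of 37, 0 over the list alone (0, and 17 lower, scaled, camera adjusted p = 0.00381), and DNA replication genes in 8 of 27, 7 over the list alone (0, and 11 lower, scaled, camera adjusted p = 0.0264), each with adjusted p = 0.895 with an estimated correlation. Of 14 cell wall genes 1 was higher and 1 lower, 1 and 0 over the list alone (1 and 10 scaled, camera adjusted p = 0.000549, adjusted p = 0.614 with an estimated correlation). Flavonoid (adjusted p = 0.000549), heat shock (0.00381) and abscisic acid (0.0264, with a median of 0.31 and a mean just below 0) also tested as down, and nitrate as up (0.0264, 10 of 12 higher, 5 scaled). Those 4 calls ended with the scaling (adjusted p = 0.0567, 0.2, 0.227 and 0.0542) and with an estimated correlation (adjusted p = 0.614, 0.408, 0.232 and 0.895).

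In all, 8941 genes differed without glucose, 8653 higher and 288 lower in gin2. With median-of-ratios scaling 5603 differed, 2585 higher and 3018 lower, and 2859 were in both. The count was 5641 without Ler minus glucose replicate 3 and 5755 without gin2 minus glucose replicate 3.

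With glucose, GPT2 fell by 3.36 ± 0.24 (adjusted p = 4.73e-10, -3.95 scaled, from 60.4 ± 11.1 RPM in Ler to 5.0 ± 1.41 RPM in gin2) and GBSS1 fell by 1.70 ± 0.21. SEN5 was 3.01 ± 0.27 higher (adjusted p = 1.09e-08, 2.36 scaled) and TPS8 2.87 ± 0.25 (2.24 scaled). SESA3 fell by 4.95 ± 0.55 (adjusted p = 3.97e-07, -5.49 scaled). TOR was at 0.52 (adjusted p = 0.0414) in RPM and -0.14 scaled, so its direction turned with the scaling, and the call in RPM ended without Ler plus glucose replicate 1 (0.50) or 3 (0.46), or any gin2 plus glucose replicate (0.47, 0.55 and 0.54).

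Sugar starvation genes were higher in 28 of 30 cases with glucose (median log2 1.47, camera adjusted p = 5.92e-14, adjusted p = 0.471 with an estimated correlation), and in 25 with median-of-ratios scaling. Ribosome biogenesis genes were higher in 24 of 29, 25 over the list alone (median 0.92, camera adjusted p = 0.00536, adjusted p = 0.882 with an estimated correlation), but with that scaling 9 were higher and 3 lower. Seed storage genes were lower in all 8 (7 by edgeR and 5 by DESeq2, median -2.35, camera adjusted p = 7.35e-25, adjusted p = 0.0804 with an estimated correlation) and root hair genes in 5 of 9 with 1 higher (median -0.74, camera adjusted p = 4.63e-09, adjusted p = 0.189 with an estimated correlation). Photosynthesis genes were higher in 7 and lower in 5 of 34 and tested as down (3 and 15 scaled, camera adjusted p = 6.15e-06, adjusted p = 0.852 with an estimated correlation). So did cell wall genes, 2 higher and 1 lower of 14, 1 and 1 over the list alone (1 and 8 scaled, camera adjusted p = 0.00221, adjusted p = 0.835 with an estimated correlation), and mitosis genes, 6 of 25 higher, 2 over the list alone (0, and 6 lower, scaled, camera adjusted p = 0.02, adjusted p = 0.913 with an estimated correlation). Flavonoid (adjusted p = 0.00607) and abscisic acid (0.00375) also tested as down, calls that ended with the scaling (adjusted p = 0.0842 and 0.121) and with an estimated correlation (adjusted p = 0.852 and 0.104). In all, 10185 genes differed, 9905 higher and 280 lower. With median-of-ratios scaling 5887 differed, 2974 higher and 2913 lower, and 3249 were in both. Without Ler plus glucose replicate 3 the count was 6550.

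The glucose effects of Ler and Col-0 were compared to ask how alike the wild types of the glucose experiments are. These came from separate experiments, so accession and experiment cannot be told apart. The effect in Ler was lower on PAP1, where it fell by 3.3 ± 0.36 (adjusted p = 2.04e-06), and on GBSS1, where it fell by 3.29 ± 0.34 (adjusted p = 1.08e-06). It was higher on SEN5 by 2.04 ± 0.33 (adjusted p = 0.000913).

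Sugar starvation genes had higher effects in 6 of 30 cases, 11 when adjusted over the list alone (12 by edgeR and 14 by DESeq2, median log2 0.50, camera adjusted p = 3.53e-16, adjusted p = 0.597 with an estimated correlation). Flavonoid genes had lower effects in 4 and higher in 1 of 11, 5 and 1 over the list alone (median -0.82, camera adjusted p = 0.00796), nitrate genes a lower effect in 1 of 12, and over the list alone also a higher one in 1 (4 higher and 1 lower scaled), with the list up (median 0.29, camera adjusted p = 0.00796), and ribosome biogenesis genes a lower effect in 1 of 29, 5 over the list alone (3 by edgeR and 4 by DESeq2, median -0.36, camera adjusted p = 9.65e-05). Limma called 0 of 37 ribosomal protein genes, with 15 lower at an unadjusted p below 0.05, 1 over the list alone, 10 by edgeR and 13 by DESeq2 (median -0.40, camera adjusted p = 3.43e-07). It called 0 of 9 root hair genes, with 6 lower at an unadjusted p below 0.05, 6 over the list alone, 1 by edgeR and 1 by DESeq2 (median -0.94, camera adjusted p = 0.000311). It called 0 of 12 ethylene perception and signalling genes, with 3 higher at an unadjusted p below 0.05, by edgeR and by DESeq2 (median 0.23, camera adjusted p = 0.00194). With an estimated correlation these 6 lists were not called (adjusted p = 0.745). Mitosis (median -0.44, camera adjusted p = 0.00152, adjusted p = 0.758 with an estimated correlation) and DNA replication (median -0.24, camera adjusted p = 0.0443, adjusted p = 0.824 with an estimated correlation) lay lower as lists. The replication and flavonoid calls ended with median-of-ratios scaling (adjusted p = 0.104 for each).

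In all, 285 of 17120 genes differed between the wild types, 106 higher and 179 lower in Ler, and 1362 with median-of-ratios scaling. The count without 1 library was 171 (Col-0 minus glucose replicate 2), 179 (Col-0 minus glucose replicate 3), 145, 141 or 166 (Col-0 plus glucose replicates 1, 2 or 3), 165 (Ler minus glucose replicate 2), 1080 (Ler minus glucose replicate 3), 164 (Ler plus glucose replicate 1) or 626 (Ler plus glucose replicate 2). Of the genes called in each wild type, 2735 rose in both, where 1108 would overlap by chance, 1740 fell in both, where 414 would, and 4 and 11 went in opposite directions. TOR was at -0.05 ± 0.21 (adjusted p = 0.978) and HXK1 at -0.27 ± 0.28 (adjusted p = 0.847).

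To ask how ethylene and glucose signalling meet, sets of glucose genes were read under ACC. A glucose-TOR set holds genes with a called glucose effect in Col-0 and a called tor interaction of the opposite sign, and a glucose-HXK1 set the same for Ler and gin2. They held 1906 raised and 1063 lowered glucose-TOR genes, and 7 raised and 36 lowered glucose-HXK1 genes. Of the lowered glucose-HXK1 genes, SEN5 rose under ACC at 2 h by 0.91 ± 0.20 and AT5G44260 by 2.93 ± 0.15. In that set 16 of 36 rose and 2 fell, 19 and 4 when adjusted over the list alone, with a median 0.33 above the other genes (camera adjusted p = 1.42e-05, adjusted p = 0.28 with an estimated correlation). The distance was 0.04 with median-of-ratios scaling and 0.05 in nuclear RPM, in sets of 232 and 207 genes. Of 1040 lowered glucose-TOR genes 156 rose and 41 fell (0.04 above the other genes, camera adjusted p = 0.00169, adjusted p = 0.28 with an estimated correlation). Of 1884 raised glucose-TOR genes 54 rose and 160 fell (-0.04, camera adjusted p = 0.00169, adjusted p = 0.286 with an estimated correlation). With sets by the wild-type effect alone these 3 calls ended (0.01, 0.02 and -0.03, adjusted p = 0.482, 0.271 and 0.087). Of the 7 raised glucose-HXK1 genes, GPT2 and XTH18 (AT4G30280) rose and AT4G34950 fell by 0.57 ± 0.12, without a call of the set (camera adjusted p = 0.368). With that scaling a set of 56 was called as down (adjusted p = 0.0258).

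At 4 h, 13 of the 36 lowered glucose-HXK1 genes rose under ACC and 5 fell, with a median 0.22 above the other genes (camera adjusted p = 0.00694, adjusted p = 0.386 with an estimated correlation). That call ended without Ler minus glucose replicate 2 (0.24), Ler plus glucose replicate 1 (0.22), gin2 minus glucose replicates 1, 2 or 3 (0.26, 0.26 and 0.10) or gin2 plus glucose replicates 2 or 3 (0.26 and 0.15). The distance was 0.04 with median-of-ratios scaling and 0.04 in nuclear RPM, where the call ended (adjusted p = 0.0543). Without Ler minus glucose replicate 3 the distance was 0.07 at each time. Without ACC 2 h replicate 3 or Ler plus glucose replicate 2 it was 0.16 or 0.19 at 2 h. Of the lowered glucose-TOR genes 233 rose and 82 fell at 4 h (0.05, camera adjusted p = 0.00522, adjusted p = 0.28 with an estimated correlation). Of the raised glucose-TOR genes 163 rose and 337 fell (camera adjusted p = 0.0123, adjusted p = 0.386 with an estimated correlation), with a median of 0.01, a mean of -0.08 and a test direction of down. With sets by the wild-type effect alone these 3 calls ended (0.02, 0.02 and -0.03, adjusted p = 0.482, 0.271 and 0.154), and that of the raised genes also with median-of-ratios scaling (-0.02, adjusted p = 0.065). Their call ended without tor plus glucose replicate 1 (2 h and 4 h) or Col-0 minus replicate 3 (4 h), each at -0.02. Their difference at 2 h was -0.03 without mock 2 h replicate 3 and -0.02 without ACC 2 h replicate 2, and at 4 h it was -0.05 without tor plus glucose replicate 2. The 7 raised glucose-HXK1 genes were not called at 4 h (camera adjusted p = 0.793), with a median of -0.05 and a mean of 0.09.

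The overlaps were tested as if genes were independent, so p can be too low. At 2 h ACC raised 156 lowered glucose-TOR genes against 56.1 by chance (Fisher's exact test, adjusted p = 4.52e-32) and lowered 160 raised ones against 72.2 (adjusted p = 2.36e-22). At 4 h these overlaps were 233 against 109 (adjusted p = 2.5e-30) and 337 against 167 (adjusted p = 8.95e-39). Raised glucose-TOR genes that ACC also raised numbered 54 against 102 at 2 h (adjusted p = 8.62e-08) and 163 against 197 at 4 h (adjusted p = 0.00903). The lowered glucose-HXK1 and glucose-TOR sets shared 24 genes against 2.11 (adjusted p = 3.3e-21, ratio 11.4). Both hold genes lowered in the wild types, which share 1740 against 414, so overlap is built in. The raised sets shared AT3G15650 and XTH18 (2 against 0.731, adjusted p = 0.202). ACC at 2 h and 4 h, from different libraries, shared 779 raised genes against 112 and 586 lowered against 65.2.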

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

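The tests chosen after the result was seen were those of RPM denominators, of organelle reads, of genes that fell in tor and of genes that respond to any treatment, and the splits of the 4 interactions. Those splits took their form after another had been seen, in which gene means were also removed and which did not exclude chance for the change of the ACC effect with time.

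Several results drew a closer look because an effect differed between groups in a test of the difference itself. The ACC effect differed between 2 h and 4 h for 7 genes, against at most 338 in the other splits (2 of 100 as large). Chance is left open there, since the earlier form of the test did not exclude it, the splits ignore the pairing of the mock libraries, and with a replicate block 4 of the 7 genes stayed called. A split that calls far more genes than the real one points to a structure of the samples. The glucose effect differed between tor and Col-0 for 3361 genes, against at most 1973 (1 of 100 splits, the real one). Between gin2 and Ler it differed for 51 genes, against at most 1592 (3 of 100 splits). With the split form chosen late, chance stays open, and structure is visible. Between Ler and Col-0 the glucose effect differed for 285 genes, against at most 6864 (7 of 100 splits), so chance was not excluded and structure is again visible. A signal outside the measured comparisons was seen in 195 of 1035 genes listed for gin2 only, whose values lie on the read step of a Ler library, and in 17 codes with an accession suffix, the highest at 128 RPM.

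The first pattern was that gin2 lay above Ler over most genes, by a median log2 of 0.555 without glucose and 0.617 with it. In RPM recomputed over nuclear reads these medians were 0.148 and 0.154, so RPM denominators that hold reads not listed are a candidate cause of most of it. Seed storage transcripts taking reads in Ler were argued against, since they took at most 0.137% of reads on listed genes in a Ler library. In the 6 Ler libraries the reads on 21 nuclear copies of mitochondrial genes rose with the share not listed (Pearson r = 0.933, exact permutation p = 0.00694, BH adjusted 0.0139, Spearman rho = 0.943, exact permutation p = 0.0167), and r was 0.708 without the 2 libraries farthest from the median. In the 6 gin2 libraries r was 0.513 (exact permutation p = 0.306, rho = 0.543, p = 0.297), so organelle transcripts may be among the unlisted reads of Ler, while a difference between genotypes and one between library batches cannot be told apart here.

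The second pattern was the smaller glucose effect in tor, read on genes chosen by a 2-fold effect in Ler. For 1092 genes that rose in Ler, the median was 1.51 in Col-0 and 0.70 in tor, a ratio of 0.4601. A higher start without glucose covered 0.0641 of the missing rise with scaling, which argues against tor already being at the glucose level. The ratio was 0.392 without the tor library that stands apart and 0.463 with median-of-ratios scaling, which argues against either as the cause. For 982 genes that fell, the medians were -1.41 and -0.93, and tor lay at -0.46 relative to all genes before glucose, 0.955 of the missing fall (0.792 with scaling), so a lower start may cover most of that part. An effect of TOR on genes that rise stays open as a hypothesis, since libraries labelled tor did not show lower TOR RPM and only 1 line was used.

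The third pattern was that ACC and glucose-TOR effects went in opposite directions. Of 815 genes called under ACC at 4 h and in a glucose-TOR set, 69.9% were opposite, with an odds ratio of same against opposite of 0.171 (95% interval 0.123 to 0.235). Genes moved alike were at most 1.03 times chance in the 4 overlaps. For glucose in Ler they were 1.41 and 1.23 (lowered) and 0.82 and 0.81 (raised) at 2 h and 4 h. Response to any treatment may contribute. Without the 3 ethylene lists 804 of 815 genes stayed (odds ratio 0.179), too many to test ethylene genes. Expression level is argued against by 570 opposite pairs (at most 344 in 1000 draws matched on it). At 2 h, 76.9% of 411 genes were opposite (odds ratio 0.0894). Opposing ethylene and glucose-TOR signalling may underlie this, a hypothesis found and tested on the same data, and the ACC seedlings were grown with glucose.

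With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1799 and 1 for ACC at 2 h, 3773 and 0 for ACC at 4 h, 11 and 0 for mock, 10883 and 0 for glucose in Col-0, 6710 and 3 for glucose in tor, 10704 and 0 for tor against Col-0 without glucose, 11881 and 0 with glucose, 4766 and 0 for glucose in gin2, 8941 and 9 for gin2 against Ler without glucose, and 10185 and 0 with glucose. In each of these 1 of 10 splits, the real one, was as large. For mock, where replicate numbers pair the samples, the splits that part every pair called 0 as well. For glucose in Ler the real count was 4986 and another split called 5198 (2 of 10). That split parts Ler plus glucose replicates 1 and 3 and minus glucose replicate 3, the libraries with the most reads not listed, from the others, and with median-of-ratios scaling it called 0 and the real split 8804.

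For the glucose sets under ACC, the distance of the set median from other genes was compared in the same way over 10 splits of the ACC and mock libraries, again too few. At 2 h the real and highest other distances were 0.0417 and 0.0597 for raised glucose-TOR genes (3 of 10), 0.0419 and 0.0449 for lowered glucose-TOR genes (2 of 10), 0.171 and 0.144 for raised glucose-HXK1 genes (1 of 10) and 0.327 and 0.222 for lowered ones (1 of 10). At 4 h they were 0.0349 and 0.0246 (1 of 10), 0.048 and 0.0405 (1 of 10), 0.0912 and 0.167 (4 of 10) and 0.225 and 0.207 (1 of 10).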

How the results depend on the processing

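Nuclear RPM, the tor library left out for its chloroplast reads and both Ler libraries numbered 3 left out were chosen after the data had been seen. No called gene reversed its call under any setting (not checked without each library in turn). Where a value moved, the cause was not tested, unless a clause below gives it.

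A 2-fold minimum lowers counts by construction. It left 220 genes for ACC at 2 h, 345 for ACC at 4 h, 6 for mock, 3277 for glucose in Col-0, 1124 in tor, 1079 for the tor interaction, 2270 and 3446 for tor against Col-0 without and with glucose, 2097 for glucose in Ler, 1995 in gin2, and 2166 and 2948 for gin2 against Ler without and with glucose.

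Median-of-ratios scaling gave 6 genes for mock, 8804 for glucose in Ler, 8060 in gin2, 336 for the gin2 interaction, 5603 and 5887 for gin2 against Ler without and with glucose, and 1362 for Ler against Col-0. On recovered reads edgeR gave 8808, 8193, 366, 5393, 6094 and 1369 for these last 6, and DESeq2 gave 8597, 8047, 490, 5446, 5998 and 1663, as well as 55 for the change of the ACC effect with time and 63 for mock. In nuclear RPM there were 9190 for glucose in Ler, 8314 in gin2, 306 for the gin2 interaction, 6709 for gin2 against Ler with glucose and 1135 for Ler against Col-0. Without both Ler libraries numbered 3 there were 7978 for glucose in gin2, where the gin2 libraries themselves were the same and the pooled spread changed, 288 for the gin2 interaction and 760 for Ler against Col-0. A fit to only the groups compared, with fewer libraries behind the spread, gave 1185 for ACC at 2 h, 5 for mock, 3173 for glucose in Ler and 9530 in gin2. Without a filter, with more genes tested, there was 1 gene for the change with time and 6 for mock.

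A replicate block gave 21 genes for mock and 83 for the gin2 interaction, and moved no other count by over 1.5 times. Of the 7 genes for the change with time, which holds the paired mock groups, 4 stayed called. No other comparison than mock had r above 0.1 in all of its pairs. Pairs with r above 0.1 numbered 2 of 3 for ACC at 2 h and for glucose in Ler, 1 of 3 for glucose in Col-0, tor and gin2 and for gin2 against Ler in each glucose state, 0 of 3 for ACC at 4 h and for tor against Col-0 in each state, 7, 6 and 7 of 18 for the change with time, the tor interaction and the gin2 interaction, and 3 of 6 for Ler against Col-0.

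Leaving out 1 library at a time gave 1336 to 1683 genes for ACC at 2 h, 2428 to 2849 for ACC at 4 h (lowest without mock 4 h replicate 3), 1 to 288 for the change with time (highest without ACC 2 h replicate 3), 0 to 13 for mock (0 by limma without mock 4 h replicate 3, with 1096 at an unadjusted p below 0.05), 2156 to 5009 for the tor interaction (without Col-0 plus glucose replicate 2 and tor plus glucose replicate 1), 20 to 212 for the gin2 interaction (without Ler minus glucose replicates 2 and 3), 5641 to 11026 for gin2 against Ler without glucose (lowest without Ler minus glucose replicate 3), 6550 to 12433 with glucose (lowest without Ler plus glucose replicate 3), and 141 to 1080 for Ler against Col-0 (without Col-0 plus glucose replicate 2 and Ler minus glucose replicate 3). Glucose in Col-0, tor, Ler and gin2 and tor against Col-0 stayed within 1.5 times of their counts without each library.

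The distance of a set's median from other genes under ACC moved, in sets remade by each glucose fit. For raised glucose-TOR genes at 2 h it ranged from -0.0603 to -0.0209 without 1 library, and at 4 h from -0.0527 to -0.0172. The calls ended at the last value of each range, without tor plus glucose replicate 1. At 4 h the call also ended with median-of-ratios scaling (-0.0235) and with sets of at least 2-fold (-0.0146). Raised glucose-HXK1 genes were called at 2 h without gin2 minus or plus glucose replicate 1 (0.346 and 5 genes for each). For these genes the distance ranged from 0.000283 to 0.346 at 2 h and -0.114 to 0.197 at 4 h (highest without gin2 minus replicate 2). With median-of-ratios scaling it was -0.051 at 2 h and -0.097 at 4 h, and in nuclear RPM -0.0463 and -0.0977, called as down at each time in sets of 56 and 62 genes, with the sign turned at 2 h. For lowered glucose-HXK1 genes at 4 h it ranged from 0.0722 to 0.324, and with median-of-ratios scaling it was 0.0365, and in nuclear RPM 0.0384 and no longer called. Sets by the wild-type effect alone, which are larger, gave -0.0297 and 0.0154 for raised and lowered glucose-TOR genes at 2 h and -0.0308 and 0.0237 at 4 h, no longer called, -0.0401 and -0.0512 for raised glucose-HXK1 genes, reversed at 2 h and called as down at each time (adjusted p = 0.0162), and 0.00894 and 0.0159 for lowered ones, no longer called.

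With an estimated correlation none of the 6 called sets was called, at unchanged distances of -0.0417, 0.0419 and 0.327 at 2 h and -0.0349, 0.048 and 0.225 at 4 h, and 3 of 123 list calls remained. Without 1 library 118 to 130 list calls were made. With median-of-ratios scaling and in nuclear RPM, 6 and 5 of the 8 list calls for glucose in Ler were kept, 8 and 7 of 9 in gin2, 5 and 5 of 5 for the gin2 interaction, 6 and 8 of 10 and 7 and 8 of 9 for gin2 against Ler without and with glucose, and 7 of 9 each for Ler against Col-0. The other comparisons kept theirs, apart from 6 of 7 for glucose in tor in nuclear RPM. The ratio of observed to expected raised genes in both the glucose-TOR and glucose-HXK1 sets, 2.74 and not past the threshold, was 3.03 with median-of-ratios scaling and 2.6 in nuclear RPM, each past it, and that of lowered genes went from 11.4 to 4.52 (109 genes) and 6.8 (95 genes). Of single genes, CYCD3;3 in tor against Col-0 without glucose turned to -0.008 with edgeR. TOR in gin2 against Ler without glucose turned from above 0 in RPM to -0.359 with median-of-ratios scaling, -0.375 with edgeR and -0.376 with DESeq2. TOR in gin2 against Ler with glucose turned to -0.141, -0.133, -0.152 and, in nuclear RPM, -0.002. Whether depth sets the 64% of simulated 2-fold rises called for glucose in Ler was not tested.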

Other observations

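A set of 5 genes, chosen after their values were seen, had at least 1 RPM in every tor library and at most 0.1 RPM in every Col-0 library of the glucose-TOR experiment, and 0 genes had the reverse. They were AT1G49640, AT1G26390, AT1G33300, AT1G71470 and AT4G19760. The lowest tor library had 4.59, 6.94, 17.2, 28.6 and 5.08 RPM. AT1G33300, AT1G71470 and AT4G19760 were at 0 in every Col-0 library of that experiment, so against the floor of 3 reads per library (0.167 RPM) they were at least 103-fold, 171-fold and 30.4-fold higher. In the ethylene experiment, on Col-0 alone, the highest library had 2.17, 8.1, 0, 0.0541 and 2.07 RPM.

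Replicate pairs within groups had Pearson correlations across genes, which are not independent replicates, of 0.968 to 0.996 over 36 pairs.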
